A study of Homo sapiens with 24 samples.

How the data were processed

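RNA of 24 samples was hybridised to Illumina bead arrays with 47231 probes. Per the labels' protocols, total RNA was column-purified, then amplified and biotin-labelled with an Illumina TotalPrep kit. The deposited values are probe intensities on a linear scale, from a lowest value of 52.6 on any array to a highest of 59613. Scanner software, background subtraction and normalization are not given in the sources used here. The array medians of the deposited intensities differed (115 to 150) and no value was under 1, so the table was taken as neither normalized between arrays nor background-subtracted. Without background subtraction the folds of dim genes are understated.

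Samples were assigned to 11 groups of line and hours at 1% oxygen from their titles, with 2 or 3 arrays per group. Intensities were taken to log2 and quantile normalized with limma 3.58.1 (statmod 1.5.0, R 4.3.3). A probe was kept if it lay above its array's median in at least 2 arrays, which left 31100 probes. Gene names came from the platform annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17110 were not listed. Entrez identifiers of 30074 probes matched a RefSeq gene table, and 0 symbols were updated. Each gene was represented by its kept probe with the highest mean over all arrays, which gave 15246 genes, and 4306 of them had more than 1 kept probe. Genes of the sex chromosomes used to infer sex are not reported here.

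Knockdown in the name of a comparison stands for the knockdown line against the shGFP line. A model of group means was fitted to all 24 arrays with limma (lmFit and eBayes), with 13 residual and 9.74 prior degrees of freedom. The contrasts were each hypoxia time against normoxia in the shGFP line, each knockdown line against shGFP at the same time and on average over its times, the knockdown lines against each other on average over 6 h and 12 h, and the change of each knockdown effect between its first and last time. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Tests were two-sided.

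The 22 gene lists were glycolysis and glucose uptake, other HIF target genes, angiogenic and inflammatory secreted factors, ERK pathway output, S phase and DNA replication, mitosis, hepatocyte secreted proteins and enzymes, cholesterol synthesis and uptake, fatty acid synthesis, ATF4 targets, ER folding and quality control, oxidative phosphorylation, interferon-stimulated genes, NF-kappaB targets, p53 targets, ribosome biogenesis, oxygen sensing and the NDRG family, collagen and matrix modification, fibroblast, endothelial and blood markers, and common reference genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the 88 tests of 22 lists in 4 comparisons. Camera compares a list with all other genes. Alternatives were camera with an estimated correlation and fry, which tests only whether a list moves on balance in a direction. For each list that passed, the adjusted p with an estimated correlation was larger, and it is printed mostly where the call was lost. The lists overlap, and several members appear in more than 1. Genes adjusted over the list alone were counted after adjustment within the list.

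Named genes followed a rule. HIF1A, NDRG3, NDRG1 and VEGFA were named in each of the 4 main comparisons, with the 8 highest and 8 lowest past the threshold whose arrays did not overlap between arms at any time. Unnamed LOC, ORF and HS. symbols were left out. Up to 4 members with the smallest p were taken from each list past the threshold and up to 2 from each other list, and the 3 highest and 3 lowest genes from each further contrast. The bound of 1.5 times the array median for understated folds was chosen after the data were seen. The hepatocyte, vimentin and keratin levels relative to the array median were chosen after their values were seen.

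The change of hypoxia-responsive genes in the knockdown lines was tested with camera on genes chosen at another time than the one compared. The adjustment over these 6 tests was added after the data were seen. The likeness of the knockdown effects was measured at crossed times because the same shGFP arrays enter both effects at the same time, and same-time values were set beside 100 simulations of unchanged groups. Groups, contrasts, lists, the naming rule and the first set of alternatives were fixed before the data were examined.

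The fit was tested on simulated data made from the real gene means and spreads, with 50 of 15246 genes changed at each size. For the 24 h hypoxia comparison it recovered 6% of genes changed 1.23-fold, 54% of those changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 4-fold. For the HIF1A knockdown average it recovered 56% at 1.23-fold and 100% at 1.5-fold, for the NDRG3 knockdown average 50% and 98%, and for the direct comparison 32% and 100%. In the real data far more genes passed (45.4% at 24 h, 38% and 43.6% in the knockdown averages, 15.8% in the direct comparison). The adjusted threshold is then less strict, so these rates check the fit and do not measure its sensitivity on the real data.

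The alternatives were values as deposited, median-centred arrays, no filter on dim probes, a stricter filter at the 60th percentile, the mean of a gene's probes, only the arrays compared, an intensity trend with robust priors, array weights, the replicate number as a block, a fold of at least 1.5, an offset of 16 before the log, and leaving out each array in turn. Background correction by normexp with the same offset, leaving out 1 array of each of the 3 groups with the widest spread, leaving out 2 gene lists from the likeness of the knockdowns, and the oxygen sensing list without HIF1A and NDRG3 were added after the data were seen.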

Results

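Gene expression was measured on Illumina bead arrays in 24 RNA samples of cells labelled Huh-7, the name of an established human hepatocellular carcinoma line. Lentiviral short hairpin RNAs against GFP (shGFP, the control), HIF1A or NDRG3 defined 3 stable lines, which were kept in 1% oxygen for up to 24 h. HIF1A encodes the oxygen-regulated subunit of a hypoxia-inducible transcription factor, and NDRG3 is a member of the N-myc downstream-regulated gene family. The shGFP line was measured in normoxia (n = 2 arrays) and after 3 h (n = 3), 6 h, 12 h and 24 h (n = 2 each) of hypoxia. The shHIF1A line was measured after 3 h (n = 3), 6 h and 12 h (n = 2 each), and the shNDRG3 line after 6 h, 12 h and 24 h (n = 2 each). Normoxia arrays of the knockdown lines, shHIF1A arrays at 24 h and shNDRG3 arrays at 3 h were not analysed here.

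The median signal per array lay between 115 and 150, and the mean signal between 769 and 1192. Arrays of the same group correlated at r = 0.9798 to 0.9973 across the 15246 genes, over 15 pairs, and no pair shared more than 1 identical value among all probes. The pair furthest apart was the shNDRG3 24 h group, whose arrays differed by a median of 0.208 on the log2 scale. The number of arrays limits the precision of every value. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values after ± are standard errors from limma on the log2 scale unless SD is named, and adjusted p-values are from limma over 15246 genes. Both use a spread per gene pooled over all groups, not the spread of the groups compared. Where a compared group of a gene lay under 1.5 times the array median, its fold is understated by background and printed as a lower bound (at least), and its log2 change is limited in the same way. Of 144 calls of named genes with another kept probe, 25 were shared by no other probe of the gene in the same direction, and 0 were opposed by one past the threshold. Several of these other probes lay near the array median on average (log2 -0.18 from it for DIO2, -0.03 for CDKN1A), where a probe can hardly show a change. Others were bright (5.54 for TUBB, 4.24 for a CD68 probe).

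Most transcripts typical of hepatocytes lay near the array median in the cells labelled Huh-7. Of 40 measured members of the hepatocyte list, 5 (12.5%) exceeded 2 times the array median in shGFP normoxia, and 6 (15%) did so in any group. Alpha-fetoprotein (AFP) lay at -0.27, apolipoprotein A-I (APOA1) at -0.42, transthyretin (TTR) at -0.08 and transferrin (TF) at -0.21 on the log2 scale relative to the array median. Albumin (ALB), by its brightest probe, lay at 0.92, with a signal of 250 ± 46 (SD, n = 2). Brighter members were the transcription factors FOXA1 at 2.70 and CEBPA at 1.13, the mitochondrial PEP carboxykinase PCK2 at 3.05, vitronectin (VTN) at 2.22 and complement C3 at 1.56. The corresponding shares were 16.7% of 12 fibroblast markers, 10% of 10 endothelial markers and 7.14% of 14 blood markers. All 17 common reference genes exceeded the same bound, as did the 32 interferon-stimulated genes. Vimentin (VIM) lay at 6.84 and keratin 8 (KRT8) at 6.16. No array of untransduced Huh-7 cells was analysed here.

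**Figure D1:**
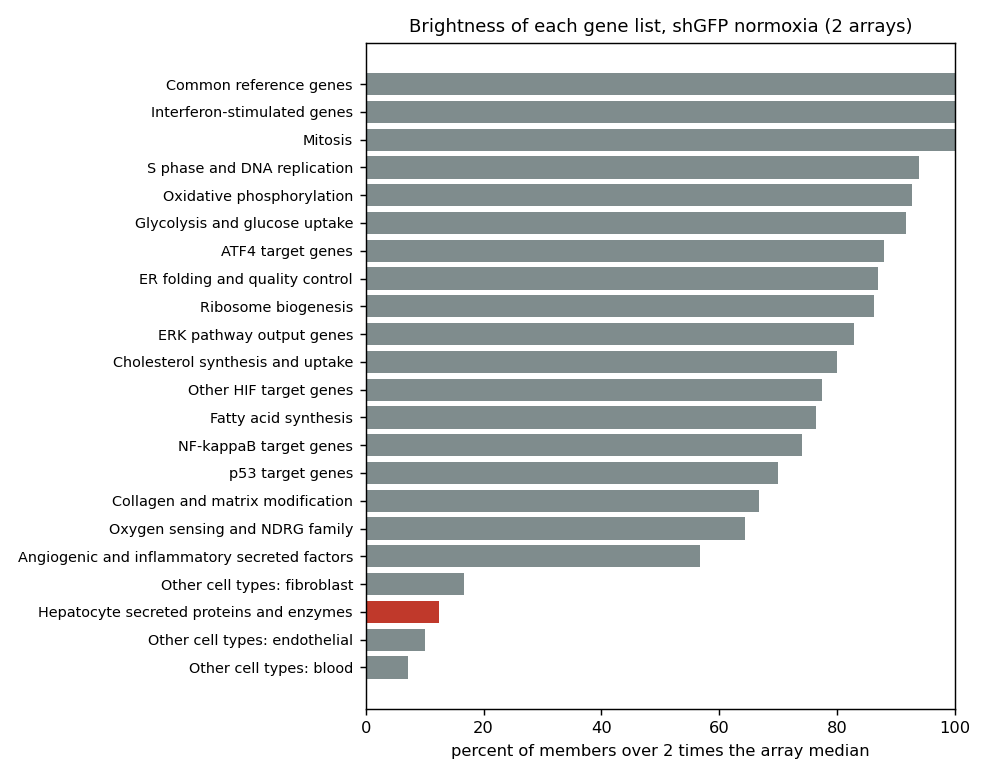
Percent of the measured members of each gene list (y axis) whose mean signal in shGFP normoxia (2 arrays) exceeded 2 times the array median (x axis), with the hepatocyte list in red. The hepatocyte list stood at 12.5%, beside the fibroblast (16.7%), endothelial (10%) and blood (7.14%) lists, while the common reference genes stood at 100%.

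Each targeted transcript was lower in its own knockdown line. HIF1A, read by its brightest probe, had a mean log2 level of 10.82 ± 0.22 (SD, n = 2) in shGFP normoxia and of 10.55 to 11.05 in the shGFP hypoxia groups. In the shHIF1A line it was 9.27 at 3 h (SD 0.35, n = 3), 8.82 at 6 h and 9.21 at 12 h, so that over the 3 times it was 2.79-fold lower than in the shGFP line (log2 -1.48 ± 0.095, adjusted p = 9.94e-12). The other HIF1A probes gave -1.12 and -0.58. NDRG3 had a mean log2 level of 10.39 to 10.75 in the shGFP groups and of 10.54 to 10.85 in the shHIF1A groups. In the shNDRG3 line it was 8.37 at 6 h, 8.55 at 12 h and 8.41 at 24 h, which was 4.54-fold lower over the 3 times (log2 -2.18 ± 0.068, adjusted p = 4.86e-18), and the other probe gave -1.83. NDRG3 did not pass the threshold in the HIF1A knockdown (0.15 ± 0.064, adjusted p = 0.066). The probes of HIF1A disagreed in the NDRG3 knockdown. Over the 3 times the brightest did not pass (log2 -0.24 ± 0.10, adjusted p = 0.0617), while the dimmer ones did (-0.50 and -0.45, adjusted p = 0.0116 and 0.0142 over all kept probes). At 24 h the dimmer probes gave -1.08 and -0.85 (adjusted p = 0.00306 and 0.0116 over all kept probes) and the brightest -0.19. These values rested on shNDRG3 24 h replicate 2. Without it the 24 h values were -0.48 and -0.36 for the dimmer probes and -0.47 for the brightest (adjusted p = 0.144, 0.331 and 0.0714 over all kept probes). The averages were then -0.30, -0.29 and -0.33 (adjusted p = 0.0428, 0.0576 and 0.00583).

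**Figure D2:**
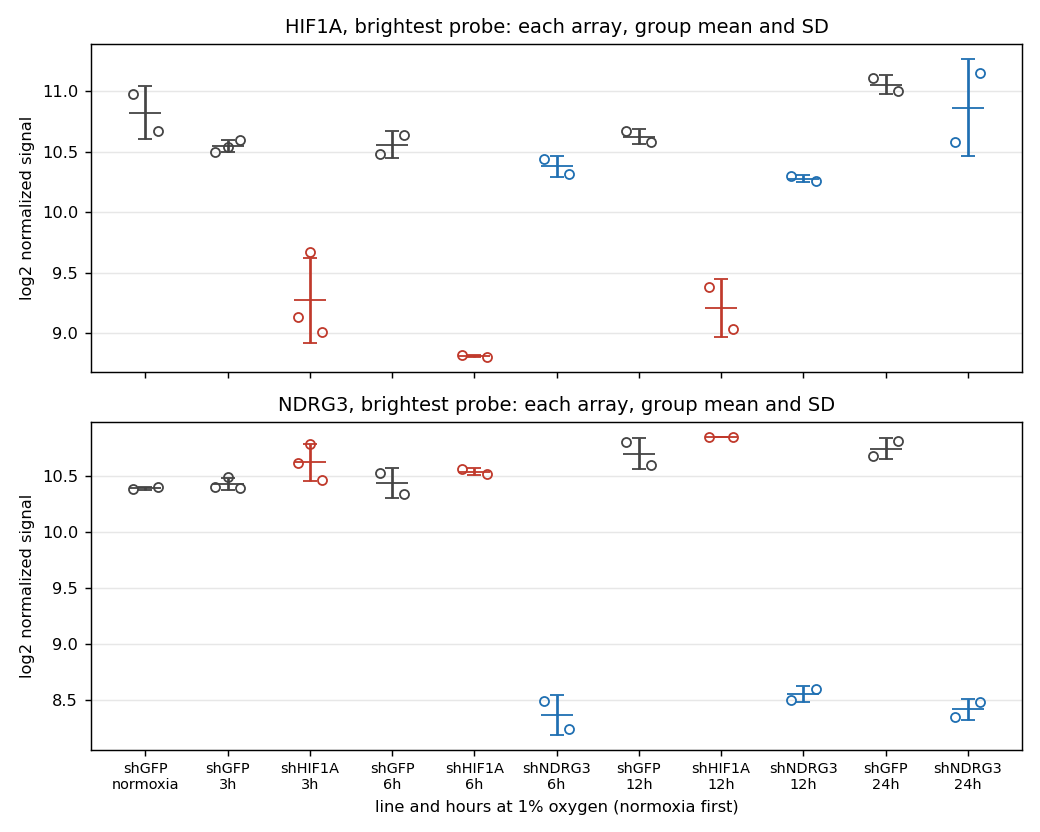
Log2 normalized signal of HIF1A and NDRG3 (brightest probe of each) on the y axis, by line and hours at 1% oxygen, with a circle per array and bars for the group mean and SD. HIF1A group means were 8.82 to 9.27 in the shHIF1A line and 10.28 or more in the other groups, and NDRG3 group means were 8.37 to 8.55 in the shNDRG3 line and 10.39 or more in the other groups.

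The shGFP line was compared with its own normoxia arrays to describe the response to hypoxia. The same normoxia arrays were the baseline at every time. A change with hours in hypoxia therefore cannot be told apart from a change with hours in culture. After 24 h, lysyl oxidase (LOX), which cross-links collagen, had risen 52.2-fold (log2 5.71 ± 0.17, adjusted p = 3e-17, n = 2 arrays per group), the largest rise among named genes. Genes of glycolysis rose together, among them enolase 2 (ENO2, 21.6-fold), aldolase C (ALDOC, 16.1-fold), the glycolytic regulator PFKFB4 (15.7-fold) and the glucose transporter SLC2A1 (5.22-fold). The secreted glycoprotein STC1 rose 17.3-fold, the growth factor binding protein IGFBP3 16.7-fold, WFDC3 at least 22.9-fold and ANKRD37 15.1-fold. The angiogenic factor VEGFA rose 5.35-fold (2.42 ± 0.19, adjusted p = 3.26e-10) and NDRG1 5.22-fold (2.39 ± 0.13, adjusted p = 3.11e-13), while HIF1A did not pass (0.23 ± 0.18, adjusted p = 0.322). NDRG3 rose 1.28-fold (0.36 ± 0.12, adjusted p = 0.0155), but its other probe did not pass (0.24 ± 0.15, adjusted p = 0.262 over all kept probes), and it gave -0.31 with the signals as deposited, which moved the median of all genes by -0.41. Strong falls were those of ANKRD1, a target of YAP signalling (at least 15-fold lower), of the ribosome assembly factors RRS1 (at least 12.7-fold) and NOP16 (10.9-fold), of MTARC1 (10.2-fold), of GPATCH4 (9.1-fold), of the interferon-induced GTPase MX2 (8.9-fold), of the CTP synthase CTPS1 (8.28-fold) and of WDR4 (7.95-fold).

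The number of genes past the threshold was 226 at 3 h (195 higher, 31 lower), 742 at 6 h (495 and 247), 3847 at 12 h (1981 and 1866) and 6917 at 24 h (3223 and 3694). PFKFB4 was among the 3 largest rises at 3 h (2.57 ± 0.11), 6 h (3.47 ± 0.12) and 12 h (3.96 ± 0.12). At 3 h it stood beside SPRY1, an inhibitor of receptor signalling (2.08 ± 0.12), and the glucose transporter SLC2A3 (2.02 ± 0.13), while AMD1 (-1.04 ± 0.14), TXNIP (-0.99 ± 0.11) and KPNA2 (-0.87 ± 0.16) fell most. At 6 h the metallothionein MT1X (2.47 ± 0.14) and the mitophagy receptor BNIP3L (2.44 ± 0.14) followed, and at 12 h LOX (3.69 ± 0.17) and ENO2 (3.53 ± 0.15). The YAP target genes CCN2 (-1.65 ± 0.14), CCN1 (-1.47 ± 0.20) and ANKRD1 (-1.43 ± 0.15) fell most at 6 h, and ANKRD1 (-2.91 ± 0.15), CCN2 (-2.31 ± 0.14) and the Wnt antagonist DKK1 (-2.25 ± 0.16) at 12 h. The arrays grew dimmer with time, and with the signals as deposited the median of all genes moved by -0.09, -0.17, -0.25 and -0.41 at the 4 times. The split was then 58 higher and 50 lower at 3 h, 193 and 630 at 6 h, 683 and 4831 at 12 h, and 1098 and 9033 at 24 h, and with median-centred arrays it was 2103 and 4475 at 24 h.

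Among the fixed lists, 38 of 39 other HIF target genes rose at 24 h and 1 fell, with the same counts adjusted over the list alone (median log2 2.20, camera adjusted p = 1.02e-26). Besides LOX they included the oxidoreductase ERO1A (9.08-fold), the lipid droplet protein HILPDA (12.3-fold) and BNIP3L (11.6-fold). Of 24 glycolysis genes, 20 rose and 1 fell, also adjusted over the list alone (median 1.30, adjusted p = 2.5e-12). In the collagen and matrix list, 13 of 19 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.86, adjusted p = 9.22e-08). Rising genes included the collagen prolyl hydroxylases P4HA2 (7.89-fold) and P4HA1 (4.36-fold) and the integrin ITGA5 (3.92-fold). Of 14 oxygen sensing and NDRG family genes, 8 rose and 0 fell, also adjusted over the list alone (median 0.45, adjusted p = 8.25e-05), among them the HIF prolyl hydroxylases EGLN3 (at least 6.07-fold) and EGLN1 (3.3-fold) and the dimerization partner ARNT2 (5.16-fold).

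Inflammatory genes rose as well. In the NF-kappaB target list, 21 of 26 rose and 1 fell (21 and 2 adjusted over the list alone, median 1.34, adjusted p = 3.5e-10), with the cytokines IL1B (11.3-fold) and IL1A (8.86-fold), the chemokine CCL20 (7.84-fold) and the feedback inhibitor TNFAIP3 (6.65-fold). Of 24 angiogenic and inflammatory secreted factors, 15 rose and 2 fell (15 and 3 adjusted over the list alone, median 0.95, adjusted p = 1.44e-06). Rising genes included angiogenin (ANG, 10.5-fold) and the cyclooxygenase PTGS2 (4.06-fold). In the ERK output list, 16 of 28 rose and 4 fell (17 and 4 adjusted over the list alone, median 0.66, adjusted p = 0.00212; adjusted p = 0.127 with an estimated correlation). Its members JUN (4.65-fold), FOS (3.72-fold) and SPRY4 rose while MYC fell 2.56-fold. SPRY4 gave -0.17 in the fit with background correction, against 1.76 without it. That fit chose each gene's brightest probe anew, so these values may come from different probes. Of 20 p53 target genes, 9 rose and 1 fell, also adjusted over the list alone (median 0.17, adjusted p = 0.0163; adjusted p = 0.127 with an estimated correlation), with the stress cytokine GDF15 (4.4-fold), SESN1 (2.78-fold), the cyclin-dependent kinase inhibitor CDKN1A (2.28-fold) and TNFRSF10B (2.09-fold) higher.

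Genes of ribosome production and of cell division fell. In the ribosome biogenesis list, 24 of 28 fell and 0 rose, also adjusted over the list alone (median -1.55, adjusted p = 1.49e-14). Falling genes included NOLC1 (7.01-fold), BYSL (5.06-fold) and DKC1 (4.84-fold). Of 32 S phase genes, 29 fell and 1 rose (median -0.94, adjusted p = 1.17e-10). Falling genes included UHRF1 (4.07-fold), CHAF1B (2.92-fold), UNG (2.68-fold by its brightest probe) and the replicative helicase subunit MCM6 (2.24-fold). Of 30 mitosis genes, 26 fell and 1 rose (median -0.70, adjusted p = 3.07e-08). Falling genes included CDC20 (3.3-fold), CENPA (3.03-fold), CCNA2 (2.54-fold) and KIF23 (2.53-fold), and both lists had the same counts adjusted over the list alone. Interferon-stimulated genes fell in 23 of 32 members with 0 higher (24 and 0 adjusted over the list alone, median -0.97, adjusted p = 1.21e-08), among them USP18 (6.08-fold), OAS2 (3.25-fold) and IFI35 (3.24-fold). In the fatty acid synthesis list, 8 of 16 fell and 4 rose, also adjusted over the list alone (median -0.39, adjusted p = 0.034; adjusted p = 0.265 with an estimated correlation), with acetyl-CoA carboxylase ACACA 4.95-fold, ME1 2.67-fold, FASN 2.3-fold and ELOVL6 2.02-fold lower.

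The remaining lists did not pass in this comparison. Cholesterol synthesis genes had 3 of 20 higher and 8 lower (adjusted p = 0.334), with INSIG1 (3.37-fold) and TM7SF2 (2.46-fold) higher. Oxidative phosphorylation genes had 1 of 41 higher and 10 lower (1 and 9 adjusted over the list alone, adjusted p = 0.154), with COX5A (-0.67 ± 0.12) and ATP5F1A (-0.61 ± 0.10) lower. ATF4 targets had 11 of 33 higher and 15 lower (adjusted p = 0.826), with the cystine transporter SLC7A11 at least 5.4-fold lower and PPP1R15A 3.5-fold higher. ER folding genes had 7 of 23 higher and 8 lower (adjusted p = 0.803), with DNAJB9 (2.31-fold) and EDEM1 (2.05-fold) higher. Common reference genes had 2 of 17 higher and 5 lower (adjusted p = 0.471), with TUBB (2.22-fold) and TFRC (2.05-fold) lower. The hepatocyte list, mostly near the array median, had 4 of 21 higher and 3 lower (2 and 3 adjusted over the list alone, adjusted p = 0.755). C3 was 2.98-fold higher and FOXA1 1.66-fold lower. Fibroblast markers had 2 of 9 higher and 1 lower (adjusted p = 0.465), led by ACTA2 (2.42-fold) and PDGFRB (at least 2.03-fold). Endothelial markers had 4 of 6 higher and 2 lower (adjusted p = 0.467), with TEK at least 2.04-fold higher and CDH5 at least 1.81-fold lower. Blood markers had 3 of 10 higher and 0 lower (adjusted p = 0.469), led by CSF1R (at least 3.29-fold) and CD68 (1.61-fold). Where no other count is given, counts adjusted over the list alone were the same, and for the ER folding and blood lists the median was below 0 while the test pointed up. A compared group lay under 1.5 times the array median for WFDC3, RRS1, ANKRD1, EGLN3, SPRY4, SLC7A11, PDGFRB, TEK, CDH5 and CSF1R at 24 h and for CCN2 at 12 h. No other kept probe shared the call of NDRG3, UNG, KIF23 or TUBB at 24 h or of KPNA2 at 3 h, but those of UNG lay near the array median. The early counts moved when an array was left out. At 3 h this held for either shGFP normoxia array, and at 6 h for normoxia replicate 1 and either shGFP 6 h array. Each omission left 1 array in its group, so the moves do not show that a single array carried the counts. At 12 h the count was 2402 without shGFP 12 h replicate 2. Median-centred arrays gave 98 and 413 genes at 3 h and 6 h, array weights 398 and 1150, and a fit on only the arrays compared 415 at 3 h.

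**Figure D3:**
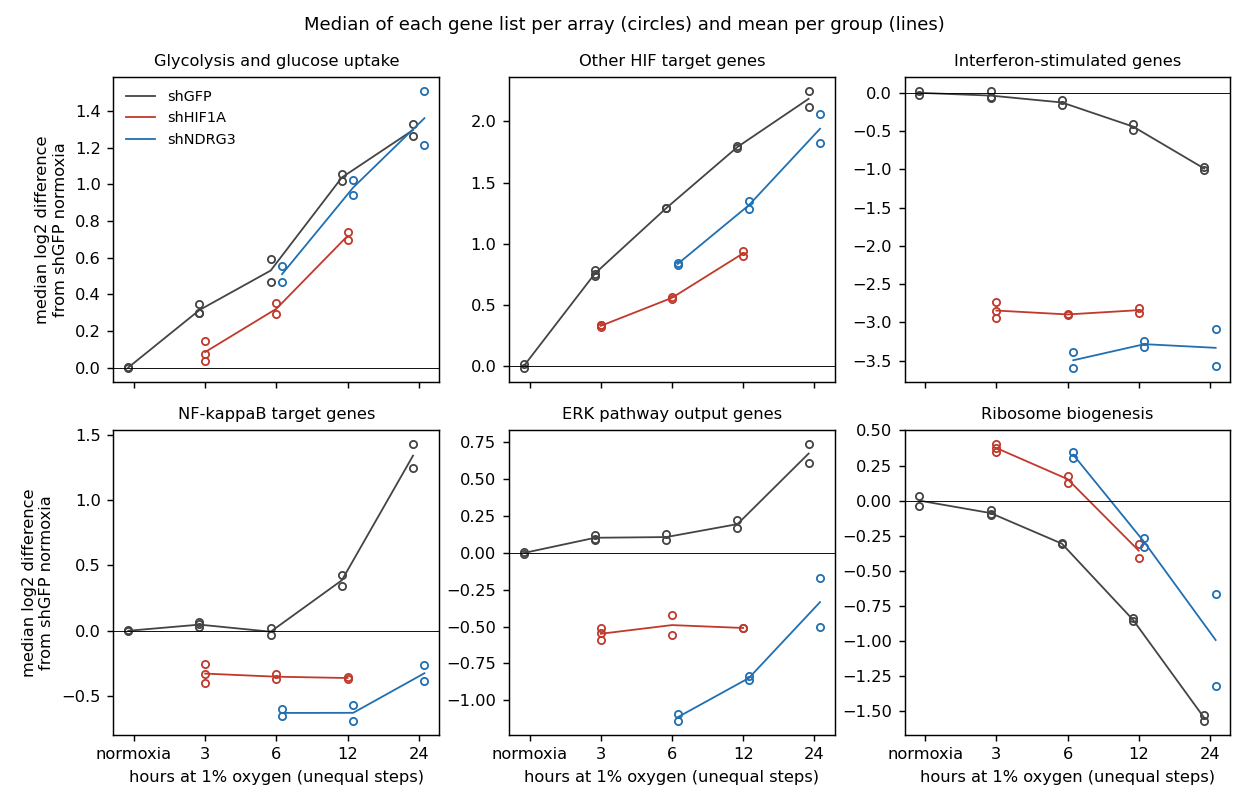
Median log2 difference from shGFP normoxia (y axis) of 6 gene lists on each array (circles) and as the group mean (lines), by line and hours at 1% oxygen (x axis, unequal steps). Interferon-stimulated genes lay between -3.60 and -2.74 on the 13 knockdown arrays, while the median of other HIF target genes was higher at each later time in each line.

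The shHIF1A line was compared with the shGFP line at 3 h, 6 h and 12 h of hypoxia. Without knockdown arrays in normoxia and with 1 hairpin per gene, this comparison of lines cannot part an effect of the knockdown from a difference present before hypoxia or an off-target effect. Interferon-stimulated genes led the decreases. OAS2, an antiviral oligoadenylate synthetase, was at least 69.6-fold lower over the 3 times (log2 -6.12 ± 0.077, adjusted p = 4.53e-25), MX2 at least 20.2-fold, IFIT3 15.7-fold, IFI44L 15.4-fold, IFIT1 14.8-fold and TRIM22 at least 14.4-fold. The peptide transporter SLC15A3 was at least 16.9-fold lower and the stress cytokine GDF15 12-fold lower. Genes that hypoxia raised were lower too, with PFKFB4 3.92-fold, ENO2 2.9-fold and the collagen prolyl hydroxylase P4HA2 2.81-fold below the shGFP line, VEGFA 1.39-fold (-0.48 ± 0.10, adjusted p = 0.000735) and NDRG1 1.17-fold (-0.23 ± 0.069, adjusted p = 0.00992). The increases were smaller and included the endothelin EDN2 (at least 3.2-fold), the deiodinase DIO2 (2.9-fold), the noncoding RNAs DANCR (2.71-fold) and DLEU1 (2.47-fold), the serotonin receptor subunit HTR3A (2.51-fold), ATPSCKMT (2.44-fold), SERPINB3 (2.44-fold) and NT5DC2 (2.39-fold).

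Between the shHIF1A and shGFP lines 5791 genes differed over the 3 times (2927 higher, 2864 lower, or 341 and 759 at 1.5-fold or more), with 3832 at 3 h (1804 and 2028), 2765 at 6 h (1279 and 1486) and 3556 at 12 h (1666 and 1890). With the signals as deposited the split was 2291 and 1136 at 3 h and 597 and 1172 at 6 h, and with median-centred arrays 2099 and 1278 at 3 h. OAS2 was among the 3 lowest genes at 3 h (-6.14 ± 0.12), 6 h (-6.24 ± 0.14) and 12 h (-5.99 ± 0.14). MX2 followed at 3 h (-4.78 ± 0.093) and 6 h (-4.38 ± 0.11), TRIM22 at 3 h (-4.23 ± 0.096), SLC15A3 at 6 h (-4.12 ± 0.12), and IFIT1 (-4.21 ± 0.31) and IFI44L (-4.16 ± 0.14) at 12 h. EDN2 (1.79 ± 0.19), ATPSCKMT (1.42 ± 0.14) and the aconitase ACO1 (1.34 ± 0.079) were highest at 3 h. DIO2 (1.77 ± 0.11), EDN2 (1.67 ± 0.24) and DANCR (1.44 ± 0.11) led at 6 h, and DIO2 (1.71 ± 0.11), DANCR (1.62 ± 0.11) and HNRNPA1 (1.59 ± 0.28) at 12 h. A compared group lay under 1.5 times the array median for OAS2, MX2, SLC15A3, TRIM22, EDN2, CCL20, TNFAIP3, DUSP6, IL1RL1, FGG, HBA2, PDGFRB, PECAM1 and VWF. No other kept probe shared the call of DIO2, ATPSCKMT, UNG, MSMO1, LSS, CDKN1A or LAMB1. The other probes of DIO2, ATPSCKMT, UNG, LSS and CDKN1A lay near the array median and say little about these calls.

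All 32 interferon-stimulated genes were lower, also adjusted over the list alone (median -2.63, adjusted p = 5.91e-49, or adjusted p = 0.000251 with an estimated correlation), HERC6 among them (7.08-fold). Of 39 other HIF target genes, 29 were lower and 3 higher, also adjusted over the list alone (median -0.51, adjusted p = 1.63e-12). Lower members included HILPDA (2.75-fold), INSIG2 (2.7-fold) and BNIP3 (2.39-fold). Of 24 glycolysis genes, 12 were lower and 1 higher (13 and 1 adjusted over the list alone, median -0.20, adjusted p = 7.16e-05; adjusted p = 0.126 with an estimated correlation). ALDOC was 2.08-fold and hexokinase HK1 1.78-fold lower. In the ERK output list, 23 of 28 were lower and 1 higher, also adjusted over the list alone (median -0.67, adjusted p = 8.59e-14), with the transcription factor ETV5 8.12-fold, cyclin CCND1 7.1-fold, the phosphatase DUSP6 at least 2.9-fold and IL1RL1 at least 2.89-fold lower. Angiogenic and inflammatory secreted factors were lower in 16 of 24 members with 0 higher, also adjusted over the list alone (median -0.59, adjusted p = 4.97e-11), and NF-kappaB targets in 19 of 26 with 0 higher (22 and 0 adjusted over the list alone, median -0.49, adjusted p = 1.88e-10). Both lists held CCL20 (at least 5.3-fold), IL6 (3.3-fold) and IL1B (2.9-fold), besides PTGS2 (4.68-fold) in the first and TNFAIP3 (at least 3.49-fold) in the second.

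In the ER folding list, 17 of 23 genes were lower and 0 higher, also adjusted over the list alone (median -0.47, adjusted p = 6.99e-08). Lower members included the chaperones DNAJB9 (1.73-fold), CALR (1.71-fold) and DNAJB11 (1.66-fold) and the disulfide isomerase PDIA6 (1.44-fold). Collagen and matrix genes were lower in 12 of 19 members with 0 higher (13 and 0 adjusted over the list alone, median -0.30, adjusted p = 4.49e-07). P4HB was 1.95-fold, ITGA5 1.91-fold and LAMB1 1.55-fold lower. Cholesterol synthesis genes were lower in 10 of 20 members and higher in 1 (11 and 2 adjusted over the list alone, median -0.19, adjusted p = 0.00444). Lower members included MSMO1 (1.85-fold), INSIG1 (1.7-fold), IDI1 (1.66-fold) and LSS (1.49-fold). Of 20 p53 targets, 8 were lower and 0 higher (10 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.00658; adjusted p = 0.0941 with an estimated correlation). CDKN1A was 2.05-fold, GADD45A 1.58-fold and TNFRSF10B 1.27-fold lower. Ribosome biogenesis genes were higher in 23 of 28 members with 0 lower (23 and 1 adjusted over the list alone, median 0.45, adjusted p = 2.11e-10). Higher members included NOLC1 (1.91-fold), DKC1 (1.79-fold), MYC (1.74-fold) and POLR1E (1.67-fold). Mitosis genes were higher in 21 of 30 members (median 0.32, adjusted p = 4.17e-08). Higher members included PLK1 (1.61-fold), HMMR (1.57-fold), CENPA (1.54-fold) and BUB1B (1.53-fold). S phase genes were higher in 19 of 32 (median 0.21, adjusted p = 3.82e-05). Higher members included UNG (1.94-fold), MCM6 (1.54-fold), POLA1 (1.37-fold) and GINS2 (1.31-fold), and in both lists 0 were lower, also adjusted over the list alone.

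The oxygen sensing and NDRG family list did not pass, with 2 of 14 higher and 4 lower (3 and 5 adjusted over the list alone, adjusted p = 0.239), although HIF1A itself and ARNT2 (1.57-fold) were lower. Fatty acid synthesis genes had 6 of 16 higher and 2 lower (6 and 4 adjusted over the list alone, adjusted p = 0.519). ACACA was 2.05-fold higher and ACSS2 1.94-fold lower. ATF4 targets had 11 of 33 higher and 12 lower (12 and 12 adjusted over the list alone, adjusted p = 0.698). PPP1R15A was 1.86-fold and TRIB3 1.81-fold lower. Oxidative phosphorylation genes had 10 of 41 higher and 2 lower (9 and 2 adjusted over the list alone, adjusted p = 0.251). CYCS was 1.76-fold and ATP5F1D 1.39-fold higher. The hepatocyte list had 2 of 21 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.602). FGG was at least 1.68-fold higher and FOXA1 1.8-fold lower, and most members lay near the array median. Blood markers had 1 of 10 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.519), with the lysosomal protein CD68 3.25-fold lower and HBA2 at least 1.52-fold higher. Fibroblast markers had 1 of 9 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.967). ACTA2 was 1.86-fold lower and PDGFRB at least 1.6-fold higher. Endothelial markers had 0 of 6 higher and 3 lower (0 and 4 adjusted over the list alone, adjusted p = 0.111). VWF was at least 1.31-fold and PECAM1 at least 1.24-fold lower. Common reference genes had 5 of 17 higher and 4 lower (5 and 5 adjusted over the list alone, adjusted p = 0.778). TFRC was 1.7-fold and EMC7 1.53-fold lower. For the ATF4 list the median was above 0 and the mean and test below it, and for the fibroblast list the mean alone was below 0. The 6 h count was 4589 with array weights, 4279 on only the arrays compared and 4286 without 1 array of each of the 3 groups with the widest spread (shHIF1A 3 h, shNDRG3 24 h and shGFP normoxia), but 1769 with the signals as deposited. It fell to between 1633 and 1743 without any 1 of its 4 arrays, shGFP 6 h replicates 1 and 2 and shHIF1A 6 h replicates 1 and 2, and the 12 h count to 2255 without shGFP 12 h replicate 2 and 2345 without shHIF1A 12 h replicate 1.

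The shNDRG3 line was compared with the shGFP line at 6 h, 12 h and 24 h of hypoxia, with the same limit on what the knockdown itself accounts for. Interferon-stimulated genes again led the decreases, with OAS2 at least 92.5-fold (log2 -6.53 ± 0.082, adjusted p = 3.95e-25), IFI27 69.8-fold, IFI44L at least 32.2-fold, IFIT1 31.2-fold, IFIT3 27.8-fold, OASL 18.9-fold and IFI44 18.3-fold lower over the 3 times. The chemokine CCL5 was 26.6-fold lower, the cytokines IL6 and IL1B were at least 16.2-fold and 16-fold lower, and the chemokine CCL20 was at least 13.7-fold lower. VEGFA was 1.5-fold lower (-0.58 ± 0.11, adjusted p = 0.000122) and NDRG1 1.17-fold lower (-0.22 ± 0.073, adjusted p = 0.0156). Increases included EDN2 (at least 4.59-fold), ACTL8 (at least 3.45-fold), DANCR (3.24-fold), KLHL13 (at least 3.05-fold), DLEU1 (2.95-fold), the arginine methyltransferase PRMT3 (2.84-fold), SLF1 (2.72-fold) and the splicing regulator MBNL3 (2.69-fold).

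Between the shNDRG3 and shGFP lines 6641 genes differed over the 3 times (3461 higher, 3180 lower, or 744 and 1128 at 1.5-fold or more), with 3862 at 6 h (1846 and 2016), 4189 at 12 h (2050 and 2139) and 5067 at 24 h (2618 and 2449). At 12 h the split was 1080 and 1986 with the signals as deposited and 1137 and 2055 with median-centred arrays. The shNDRG3 24 h arrays lay further apart, with a median SD per gene of 0.147 against 0.068 at 6 h and 0.071 at 12 h. The pooled standard errors understate that spread, so the larger 24 h count does not show a larger difference of the lines. It was 1795 on only the arrays compared. OAS2 was among the 3 lowest genes at 6 h (-7.12 ± 0.14), 12 h (-6.84 ± 0.14) and 24 h (-5.63 ± 0.14), beside IFI27 at 6 h (-6.55 ± 0.48) and 12 h (-6.79 ± 0.48), IFIT3 at 6 h (-5.66 ± 0.20) and IFI44L at 12 h (-5.31 ± 0.14). At 24 h IL1B gave -5.66 ± 0.14 and CCL20 -5.28 ± 0.17. EDN2 was among the 3 highest at 6 h (2.08 ± 0.24) and 12 h (2.91 ± 0.24), beside KLHL13 (1.97 ± 0.17) and ACTL8 (1.87 ± 0.12) at 6 h and DANCR (2.02 ± 0.11) and ACTL8 (1.96 ± 0.12) at 12 h. SLF1 (2.33 ± 0.14), the sarcomere protein MYPN (2.07 ± 0.10) and LINC02783 (2.06 ± 0.13) were highest at 24 h. A compared group lay under 1.5 times the array median for OAS2, MX2, IFI44L, IL1B, IL6, IL1A, CCL20, EDN2, ACTL8, KLHL13, ETV5, DUSP6, ARNT2, NUPR1, VTN, CSF1R, PDGFRB, PECAM1 and VWF. No other kept probe shared the call of UNG, but its other probes lay near the array median.

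All 32 interferon-stimulated genes were lower, also adjusted over the list alone (median -2.73, adjusted p = 4.76e-41, or adjusted p = 0.000272 with an estimated correlation), MX2 (at least 12.1-fold) and HERC6 (8.12-fold) among them. NF-kappaB targets were lower in 22 of 26 members and higher in 1, also adjusted over the list alone (median -1.08, adjusted p = 7.01e-16). IL1A was at least 9.42-fold lower. In the ERK output list, 23 of 28 were lower and 1 higher, also adjusted over the list alone (median -1.08, adjusted p = 2.51e-14). Lower members included ETV5 (at least 9.09-fold), KLF6 (5.81-fold), PHLDA1 (5.46-fold) and DUSP6 (at least 4.01-fold). Angiogenic and inflammatory secreted factors were lower in 18 of 24 members with 0 higher, also adjusted over the list alone (median -1.05, adjusted p = 7.53e-13), PTGS2 (4.31-fold) among them. Of 39 other HIF target genes, 21 were lower and 5 higher (22 and 7 adjusted over the list alone, median -0.22, adjusted p = 0.0024; adjusted p = 0.133 with an estimated correlation), with the carbonic anhydrase CA12 3.27-fold, LOX 2.25-fold, ERO1A 2.13-fold and BHLHE40 1.7-fold lower. The glycolysis list did not pass, with 4 of 24 higher and 6 lower, also adjusted over the list alone (adjusted p = 0.755), and with the glycolytic enzymes PFKM (1.96-fold) and GPI (1.54-fold) higher.

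In the collagen and matrix list, 18 of 19 genes were lower and 0 higher, also adjusted over the list alone (median -0.61, adjusted p = 1.02e-09). Lower members included ITGA5 (2.18-fold), LAMB1 (1.91-fold), the basement membrane collagen COL4A1 (1.87-fold) and P4HB (1.63-fold). ER folding genes were lower in 16 of 23 members with 0 higher (17 and 0 adjusted over the list alone, median -0.60, adjusted p = 2.13e-07). DNAJB9 was 2.57-fold, the transcription factor XBP1 2.14-fold, CALR 1.66-fold and PDIA6 1.63-fold lower. Cholesterol synthesis genes were lower in 12 of 20 members and higher in 2, also adjusted over the list alone (median -0.29, adjusted p = 0.000804). Lower members included MSMO1 (3.57-fold), IDI1 (2.72-fold), LSS (2.09-fold) and squalene epoxidase SQLE (2.03-fold). Of 20 p53 targets, 8 were lower and 1 higher, also adjusted over the list alone (median -0.06, adjusted p = 0.00916; adjusted p = 0.102 with an estimated correlation). GDF15 was 10.7-fold, CDKN1A 3.67-fold, TNFRSF10B 1.89-fold and GADD45A 1.81-fold lower. In the oxygen sensing and NDRG family list, 6 of 14 were lower and 0 higher (9 and 1 adjusted over the list alone, median -0.22, adjusted p = 0.00944). The list holds NDRG3 itself, and without both hairpin targets it did not pass, with 5 of 12 lower and 0 higher (median -0.21, adjusted p = 0.0627). ARNT2 was at least 3.1-fold, the HIF subunit EPAS1 1.84-fold and HIF1AN 1.27-fold lower besides NDRG3. Ribosome biogenesis genes were higher in 26 of 28 members (median 0.62, adjusted p = 8.38e-12). Higher members included BOP1 (2.31-fold), POLR1E (2.21-fold), DKC1 (2.03-fold) and MYC (1.89-fold). Mitosis genes were higher in 26 of 30 (median 0.43, adjusted p = 2.7e-09). Higher members included CENPF (1.81-fold), HMMR (1.78-fold), CENPA (1.68-fold) and CDC20 (1.51-fold). S phase genes were higher in 23 of 32 members and lower in 1 (median 0.35, adjusted p = 1.36e-07). Higher members included UNG (2.29-fold), GINS2 (1.76-fold), MCM6 (1.59-fold) and POLA1 (1.59-fold), and these 3 lists had the same counts adjusted over the list alone.

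Of the lists that did not pass, oxidative phosphorylation had 15 of 41 genes higher and 6 lower, also adjusted over the list alone (adjusted p = 0.0684). NDUFA10 was 1.5-fold and NDUFA9 1.48-fold higher. ATF4 targets had 10 of 33 higher and 13 lower (10 and 14 adjusted over the list alone, adjusted p = 0.148). NUPR1 was at least 2.61-fold and DDIT3 2.25-fold lower. Fatty acid synthesis genes had 6 of 16 higher and 3 lower (6 and 4 adjusted over the list alone, adjusted p = 0.519). ACSS2 was 2.28-fold lower and ACACA 2.21-fold higher. The hepatocyte list had 2 of 21 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.543). VTN was at least 5.18-fold lower and CEBPA 1.96-fold higher. Blood markers had 0 of 10 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.214). CD68 was 3.46-fold and CSF1R at least 1.42-fold lower. Endothelial markers had 0 of 6 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.151). PECAM1 was at least 1.88-fold and VWF at least 1.67-fold lower. Fibroblast markers had 1 of 9 higher and 2 lower (1 and 1 adjusted over the list alone, adjusted p = 0.625). ACTA2 was 2.73-fold lower and PDGFRB at least 1.6-fold higher. Common reference genes had 7 of 17 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.555). EMC7 was 1.56-fold lower and RPL13A 1.38-fold higher. The median and the test differed in sign for the glycolysis, hepatocyte and blood lists, whose tests pointed down. The 24 h count was 1795 when only the arrays compared entered the fit and 2853 with array weights.

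The knockdown lines were compared directly at 6 h and 12 h, without the shGFP arrays, to describe where they differed. Here too an effect of a knockdown cannot be parted from a difference present before hypoxia or an off-target effect. Several HIF target and glycolysis genes were lower in the shHIF1A than in the shNDRG3 line, although the glycolysis list as a whole lost its call with an estimated correlation (adjusted p = 0.0625). Lower were the heme oxygenase HMOX1 (5.44-fold, log2 -2.44 ± 0.095, adjusted p = 7.39e-15), ALDOC (2.74-fold), the pyruvate dehydrogenase kinase PDK3 (2.58-fold), PFKFB4 (2.52-fold), BNIP3 (2.44-fold), HILPDA (2.41-fold) and the glycogen-targeting subunit PPP1R3C (2.32-fold). RCOR2 (3.06-fold), ACTL8 (2.59-fold), the tropomyosin TPM1 (2.58-fold) and GKN2 (2.57-fold) were also lower. Higher in the shHIF1A line were the secretase BACE2 (8.98-fold), IFI27 (8.35-fold), the glycoprotein hormone subunit CGA (7.32-fold), SERPINB3 (at least 5.46-fold), the calcium-binding protein S100A9 (at least 5.13-fold), the ectonucleotidase NT5E (at least 5.08-fold) and KLF6 (4.76-fold). HIF1A was 2.49-fold lower (-1.32 ± 0.12, adjusted p = 2.85e-08) and NDRG3 4.73-fold higher (2.24 ± 0.083, adjusted p = 4.47e-15), while NDRG1 (0.14 ± 0.09, adjusted p = 0.377) and VEGFA (0.21 ± 0.14, adjusted p = 0.379) did not pass. In all, 2405 genes differed (1299 higher, 1106 lower, or 382 and 180 at 1.5-fold or more), and the split was 1123 and 564 with the signals as deposited and 1333 and 509 with median-centred arrays.

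Of 24 glycolysis genes, 12 were lower and 2 higher in the shHIF1A line (14 and 3 adjusted over the list alone, median -0.25, adjusted p = 6.69e-07; adjusted p = 0.0625 with an estimated correlation). ENO2 was 1.75-fold and HK1 1.67-fold lower. Of 39 other HIF target genes, 18 were lower and 5 higher (18 and 6 adjusted over the list alone, median -0.20, adjusted p = 7.14e-07). Interferon-stimulated genes, lower than in the shGFP line in both, were higher in the shHIF1A than in the shNDRG3 line in 23 of 32 members and lower in 1 (25 and 1 adjusted over the list alone, median 0.54, adjusted p = 7.93e-16). IRF9 was 2.83-fold, IFIT3 2.61-fold and IFI44L at least 2.24-fold higher and MX1 1.86-fold lower. ERK outputs were higher in 14 of 28 members and lower in 1, also adjusted over the list alone (median 0.26, adjusted p = 9.28e-08). Higher members included PHLDA1 (2.44-fold), IER3 (1.88-fold) and ETV5 (at least 1.66-fold). NF-kappaB targets were higher in 14 of 26 and lower in 1 (16 and 2 adjusted over the list alone, median 0.32, adjusted p = 7.15e-08), and angiogenic and inflammatory secreted factors in 11 of 24 and lower in 2 (12 and 2 adjusted over the list alone, median 0.21, adjusted p = 3.18e-07). IL1A was at least 4.01-fold, IL6 at least 3.72-fold, IL1B at least 2.89-fold, VEGFC at least 2.11-fold and CXCL2 at least 1.79-fold higher. Collagen and matrix genes were higher in 8 of 19 and lower in 1 (11 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.000673). TGFBI was 1.84-fold, COL5A1 1.66-fold and LAMB1 1.53-fold higher and P4HA2 1.77-fold lower.

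Further lists passed camera only with the preset correlation. ATF4 targets were higher in 7 of 33 members and lower in 2, also adjusted over the list alone (median 0.16, adjusted p = 0.00229; adjusted p = 0.133 with an estimated correlation). SLC38A2 was 1.77-fold, NUPR1 at least 1.56-fold and CEBPB 1.54-fold higher and SLC7A11 1.35-fold lower. Ribosome biogenesis genes were lower in 6 of 28 with 0 higher (7 and 0 adjusted over the list alone, median -0.15, adjusted p = 0.00212; adjusted p = 0.232 with an estimated correlation). Lower members included UTP15 (1.32-fold), PNO1 (1.29-fold), PPAN (1.26-fold) and FBL (1.26-fold). Oxidative phosphorylation genes were lower in 6 of 41 and higher in 1, also adjusted over the list alone (median -0.08, adjusted p = 0.0332; adjusted p = 0.0578 with an estimated correlation). Lower members included NDUFC1 (1.45-fold), NDUFB6 (1.27-fold), NDUFB8 (1.24-fold) and NDUFA2 (1.22-fold). Cholesterol synthesis genes were higher in 7 of 20 and lower in 2 (7 and 3 adjusted over the list alone, median 0.15, adjusted p = 0.0354; adjusted p = 0.0824 with an estimated correlation). MSMO1 was 1.92-fold, SQLE 1.35-fold and LSS 1.33-fold higher and INSIG1 1.51-fold lower.

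The lists that did not pass were led by few genes. Oxygen sensing and NDRG family genes had 3 of 14 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0741). ARNT2 was at least 2.01-fold higher. Mitosis genes had 0 of 30 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.0846). CENPF was 1.33-fold and BUB1 1.32-fold lower. S phase genes had 3 of 32 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.469). RRM2 was 1.48-fold and TYMS 1.33-fold higher. Fatty acid synthesis genes had 3 of 16 higher and 3 lower (5 and 3 adjusted over the list alone, adjusted p = 0.713), with SCD and ACSS2 each 1.36-fold higher. ER folding genes had 1 of 23 higher and 1 lower (1 and 0 adjusted over the list alone, adjusted p = 0.713), which were XBP1 (1.41-fold higher) and DERL1 (1.19-fold lower). The p53 targets had 3 of 20 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.559). CDKN1A was 2.22-fold higher and SESN1 1.62-fold lower. The hepatocyte list had 3 of 21 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.529). VTN was at least 3.98-fold and FGG at least 1.61-fold higher. Fibroblast markers had 1 of 9 higher and 0 lower (adjusted p = 0.183), namely ACTA2 (1.53-fold), while LUM gave 0.20 ± 0.12 (adjusted p = 0.299). Endothelial markers had 2 of 6 higher and 1 lower (adjusted p = 0.168). PECAM1 was at least 1.56-fold and VWF at least 1.41-fold higher. Blood markers had 2 of 10 higher and 0 lower (adjusted p = 0.354), namely HBA2 (at least 1.55-fold) and CD68 (1.34-fold). Common reference genes had 0 of 17 higher and 1 lower (adjusted p = 0.984), namely TFRC (1.28-fold), while HPRT1 gave -0.19 ± 0.071 (adjusted p = 0.077), and these last 4 lists had the same counts adjusted over the list alone. In this comparison a compared group lay under 1.5 times the array median for SERPINB3, S100A9, NT5E, IL1A, IL1B, IL6, VEGFC, CXCL2, IFI44L, ETV5, ARNT2, NUPR1, VTN, FGG, LUM, HBA2, PECAM1 and VWF. No other kept probe shared the call of ETV5, MSMO1, INSIG1, LSS, IFI44L, CDKN1A, LAMB1 or CD68, but those of LSS and CDKN1A lay near the array median. For the hepatocyte and blood lists the median was below 0 and the mean and test above it, and for the reference genes the mean alone was below 0. The count of differing genes was 3773 with array weights, and 3892 without 1 array of each of the 3 groups with the widest spread, an alternative added after the data were seen.

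Genes that responded to hypoxia in the shGFP line were then followed in the knockdown lines, with the genes chosen on arrays that did not enter the knockdown comparison. The log2 change in hypoxia had to be at least 1, and the 6 camera tests were adjusted together. Of 965 genes raised at 24 h, 606 were lower and 65 higher in the shHIF1A line (median -0.31, adjusted p = 2.26e-25, or adjusted p = 0.0253 with an estimated correlation). Of 932 lowered genes, 582 were higher and 105 lower (median 0.31, adjusted p = 1.92e-16, or adjusted p = 0.0772 with an estimated correlation). The shNDRG3 line was read over 6 h and 12 h for the same genes. There, 562 of the raised genes were lower and 63 higher (median -0.35, adjusted p = 5.31e-24, or adjusted p = 0.0253 with an estimated correlation). Of the lowered genes, 619 were higher and 107 lower (median 0.42, adjusted p = 6.78e-18, or adjusted p = 0.0772 with an estimated correlation). At 24 h, 131 of 301 genes raised by 12 h of hypoxia were lower in the shNDRG3 line and 39 higher (median -0.27, adjusted p = 6.18e-08, or adjusted p = 0.119 with an estimated correlation). Of the 156 genes lowered by 12 h, 80 were higher and 29 lower (median 0.41, adjusted p = 1.39e-05, or adjusted p = 0.167 with an estimated correlation). With 1 array left out at a time these 24 h medians ranged from -0.43 to -0.12 and from 0.24 to 0.52.

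The knockdown changes of both lines were compared across genes at crossed times, which share no array, although genes are not independent replicates. Both were still taken against the shGFP line. A standing difference of that line alone could therefore give a correlation and shared genes, without any likeness of the knockdown effects. Interferon-stimulated genes lay at the low end of both. Spearman's correlation was 0.628 between HIF1A knockdown at 6 h and NDRG3 knockdown at 12 h, and 0.6 between HIF1A knockdown at 12 h and NDRG3 knockdown at 6 h, with jackknife SDs of 0.0505 and 0.0546. In the former, 1078 genes were lower in both against 208 for independent lists, and 887 were higher in both against 172. In the latter, 1200 genes were lower in both against 250, and 988 were higher in both against 202. At the same time, where both share the shGFP arrays, the correlation was 0.733 at 6 h and 0.727 at 12 h, against 0.479 simulated for unchanged groups over the same controls. The covariance was 0.154 and 0.164, against 0.00966 simulated.

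**Figure D4:**
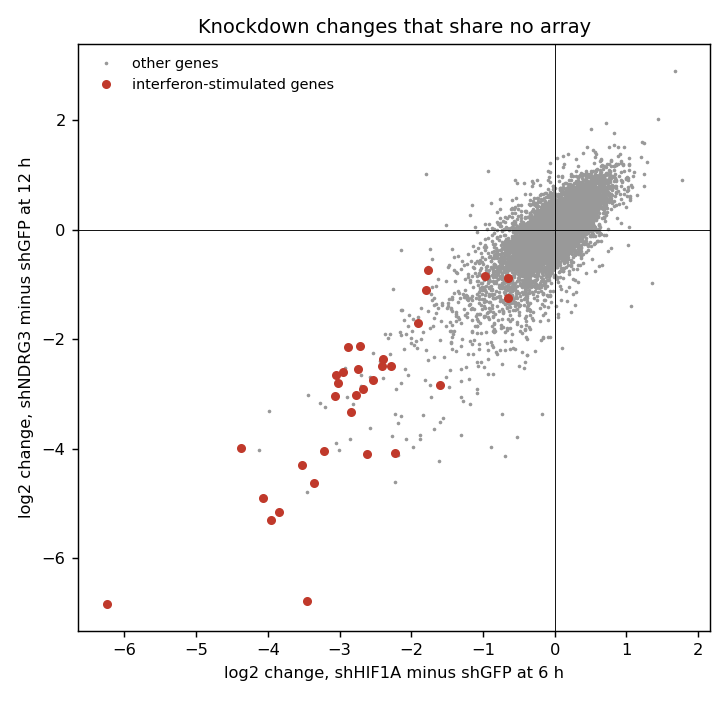
Log2 change of each gene in the shHIF1A line at 6 h (x axis) and in the shNDRG3 line at 12 h (y axis), each against shGFP at the same time, with interferon-stimulated genes in red. Spearman's correlation across genes was 0.628, and OAS2 lay at -6.24 and -6.84.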

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

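Tests of shared control arrays, of a delayed hypoxia response, of the shGFP line itself and of the brightness of hepatocyte genes were chosen only after the result was seen.

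The effect of a knockdown differed between times, by the interaction test of limma. For NDRG3, 1627 genes had a different effect at 24 h than at 6 h (919 higher, 708 lower), and 40 of the 84 genes named for that knockdown were among them. ISG20 (2.89), MX2 (2.67) and ANKRD1 (2.22) gave the largest positive log2 differences, and S100A8 (-3.26), IL1B (-3.06) and IL32 (-2.65) the largest negative ones. In the shNDRG3 line all of these but ISG20 lay under 2 times the array median at 6 h or at both times, so their values mostly follow the shGFP line and do not measure a change of the knockdown effect. The count was 1080 without shGFP 6 h replicate 2, 1067 without shNDRG3 6 h replicate 1 and 3140 without shNDRG3 24 h replicate 1, and the split was 612 higher and 306 lower with median-centred arrays. For HIF1A, 187 genes had a different effect at 12 h than at 3 h (84 higher, 103 lower), and 10 of the 81 genes named for that knockdown were among them. PPP1R10 (1.30), ID1 (1.15) and ANKRD1 (1.14) gave the largest positive differences, and S100A9 (-1.40), SYT7 (-1.23) and SLC45A3 (-1.18) the largest negative ones. None of the 3 other kept SYT7 probes shared its call, but they lay near the array median (-0.08, -0.17 and 0.42 from it). In the shHIF1A line ANKRD1 at 12 h and SLC45A3 at both times lay under the same bound, which limits their values too. This count was 105 without shGFP 3 h replicate 2, 103 without its replicate 3, 57 and 58 without shGFP 12 h replicates 1 and 2, and 59 and 92 without shHIF1A 12 h replicates 1 and 2. Its split was 8 higher and 29 lower with the signals as deposited and 13 and 30 with median-centred arrays.

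The knockdown lines differed directly in 2405 genes. Of 18 splits of these arrays within times, 1 reached that count, the real split itself, and the highest other gave 19, but 18 splits are too few for a share under 0.05. The 3832 genes of the HIF1A knockdown at 3 h were reached by 1 of 10 splits, the real one, with 0 genes as the highest other, and 10 splits are likewise too few. For the HIF1A knockdown average, 1 of 100 splits drawn, the real one, reached 5791 genes, with 3860 as the highest other. For the NDRG3 knockdown average, 1 of 100 reached 6641, with 3893 as the highest other. The median of the other splits was 0 genes for both averages, so the counts followed the line labels. Splits that mix lines add the difference of the lines to the spread, which favours the real split. Chance differences between cultures are not excluded, since the arrays of a group may be technical replicates.

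Probes with no gene listed, which entered no comparison of genes, also passed the threshold. There were 1784 in hypoxia at 24 h, 1692 in the HIF1A knockdown average, 2000 in the NDRG3 knockdown average and 470 between the knockdown lines.

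Interferon-stimulated genes were lower in both knockdown lines than in the shGFP line. Chance values of the shared shGFP arrays were argued against by a correlation of 0.6 at crossed times, which share no array, but it was taken over all genes. Within the list, all 32 members were lower at 3 h for shHIF1A and at 24 h for shNDRG3. These comparisons share no shGFP array either. A hypoxia response delayed as a whole would raise these genes, which fell with hypoxia, whereas their median in the HIF1A knockdown was -2.63. The gap was there at the first time measured, with a median of -2.84 at 3 h for shHIF1A and -3.38 at 6 h for shNDRG3. Hypoxia had by then moved these genes by -0.05 and -0.16 in the shGFP line. At the last times the gap was smaller (-2.43 and -2.16). A difference of the shGFP line itself, present before hypoxia, cannot be told apart from an effect of the knockdowns, because no knockdown arrays in normoxia were analysed here. The knockdown lines differed from each other by a median of 0.54. An off-target effect of a hairpin may also contribute and was not tested, since each gene had 1 knockdown line.

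Hepatocyte genes lay near the array median in the arrays labelled Huh-7. Arrays that fail to read even bright genes were argued against by the common reference genes, 100% of which exceeded 2 times the array median. These genes had a median log2 of 6.27 over the array median in shGFP normoxia. They therefore cannot show whether weak transcripts were read. Loss of hepatocyte transcripts in hypoxia was argued against by the normoxia arrays, where 12.5% of the list exceeded that bound. Cells that do not make most hepatocyte transcripts, by line identity or by loss of them in culture, stay open as explanations that were not tested.

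Glycolysis genes were lower in the HIF1A than in the NDRG3 knockdown line, but the list's adjusted p was 0.0625 with an estimated correlation. Normalization between arrays was argued against by a median of -0.26 with the weaker of the other scalings, and a single deciding array by a median of -0.22 at the weakest omission. Less HIF1A in its own knockdown line stays open as the biological explanation and was not tested, because the hairpin itself sets that level.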

How the results depend on the processing

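Background correction and the omission of 3 arrays, of 2 gene lists or of the hairpin targets from a list were chosen only after the data were seen. Both targets kept their direction and call in 44 of 44 alternatives. Of 6912 values for named genes, 6834 kept direction and call, 64 lost the call, 12 gained it and 2 reversed: NDRG3 in hypoxia at 24 h (-0.31 as deposited, against 0.36) and SPRY4 in hypoxia at 24 h (-0.17 in the fit with background correction, against 1.76). Fits on other scalings chose the brightest probe anew, so a reversed value may come from another probe. Of 1980 list tests, 1921 kept their call, 23 lost it and 36 gained it, and 0 reversed. Camera with an estimated correlation alone gave 12 of the 23 lost calls, and fry gave 25 of the 36 gained. Omissions of a single array made up 828 of the 1921 kept calls, and lists that had not passed were counted too. Most named genes were chosen for large changes or small p-values, which favours stable calls. These totals therefore do not measure how firm the passing calls were. Of 290 gene counts, 232 stayed within 1.5 times the reported one. Signal over background limits folds of dim genes, and the cause was not tested for any change below except the fold of 1.5, which is stricter by construction.

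With the signals as deposited the counts were 108 for genes changed by hypoxia 3 h, 1769 for genes changed by HIF1A knockdown 6 h, 780 for genes whose NDRG3 knockdown effect differs between 24 h and 6 h, and 37 for genes whose HIF1A knockdown effect differs between 12 h and 3 h. With median-centred arrays they were 98 for genes changed by hypoxia 3 h, 413 for genes changed by hypoxia 6 h, and 918 and 43 for the NDRG3 and HIF1A effects over time. Array weights gave 398 and 1150 for genes changed by hypoxia 3 h and 6 h, 4589 for HIF1A knockdown 6 h, 2853 for genes changed by NDRG3 knockdown 24 h, 3773 for genes that differ between HIF1A and NDRG3 knockdown averaged over 6 and 12 h, and 969 and 659 for the effects over time. Fits on only the arrays compared gave 415, 4279, 1795 and 592 for hypoxia 3 h, HIF1A knockdown 6 h, NDRG3 knockdown 24 h and the NDRG3 effect over time. Background correction gave 59 for the HIF1A effect over time. Without 1 array of each of the 3 groups with the widest spread (shHIF1A 3 h replicate 2, shNDRG3 24 h replicate 2 and shGFP normoxia replicate 1, of which the last 2 could not be told from their only mates) the counts were 4286 for HIF1A knockdown 6 h, 3892 for the direct comparison, and 2967 and 713 for the effects over time.

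A fold of at least 1.5 left 118, 358, 1826 and 4212 genes changed by hypoxia 3 h, genes changed by hypoxia 6 h, genes changed by hypoxia 12 h and genes changed by hypoxia 24 h. It left 1100, 1120 and 1546 genes changed by HIF1A knockdown 3 h, genes changed by HIF1A knockdown 6 h and genes changed by HIF1A knockdown 12 h, and 1100 genes changed by HIF1A knockdown averaged over 3, 6 and 12 h (341 higher, 759 lower). It left 1842, 2012 and 2698 genes changed by NDRG3 knockdown 6 h, genes changed by NDRG3 knockdown 12 h and genes changed by NDRG3 knockdown 24 h, 1872 genes changed by NDRG3 knockdown averaged over 6, 12 and 24 h (744 and 1128), and 562 in the direct comparison (382 and 180). An estimated correlation gave 6 lists in the direct comparison, and fry gave 20 for NDRG3 and 17 for the direct comparison. Without both hairpin targets, outside those counts, the oxygen sensing list lost its call for NDRG3 (adjusted p = 0.0627). With an estimated correlation the medians of hypoxia-responsive genes lost their call before adjustment at 0.31 (p = 0.0515) for lowered genes in the HIF1A knockdown, and at -0.27 (p = 0.0989) and 0.41 (p = 0.167) for NDRG3 knockdown at 24 h, and after adjustment also at 0.42 for lowered genes in the NDRG3 knockdown at 6 h and 12 h. The crossed-time correlations were 0.542 and 0.516 without the filter on dim probes, and 0.733 and 0.727 at the same time.

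With each array left out in turn, a group of 1 array being assumed to vary like the others, counts ranged from 92 to 411 for hypoxia 3 h (92 and 411 without shGFP normoxia replicates 1 and 2), from 338 to 655 for hypoxia 6 h (338 without shGFP normoxia replicate 1, 369 and 342 without shGFP 6 h replicates 1 and 2), from 2402 to 3104 for hypoxia 12 h (2402 without shGFP 12 h replicate 2), from 1633 to 1743 for HIF1A knockdown 6 h (each of its 4 arrays), from 2255 to 2642 for HIF1A knockdown 12 h (2255 without shGFP 12 h replicate 2, 2345 without shHIF1A 12 h replicate 1), from 1067 to 3140 for the NDRG3 effect over time (1080 without shGFP 6 h replicate 2, 1067 without shNDRG3 6 h replicate 1, 3140 without shNDRG3 24 h replicate 1) and from 57 to 168 for the HIF1A effect over time (105 and 103 without shGFP 3 h replicates 2 and 3, 57 and 58 without shGFP 12 h replicates 1 and 2, 59 and 92 without shHIF1A 12 h replicates 1 and 2). The medians of hypoxia-responsive genes in the NDRG3 knockdown at 24 h ranged from -0.43 to -0.12 for raised and from 0.24 to 0.52 for lowered genes (-0.12 and 0.25 without shNDRG3 24 h replicate 2).

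The replicate numbers gave little sign of pairing, which is not excluded for some groups. Over 111 pairs with the same number in different groups the deviations correlated at a mean of 0.015 (-0.0953 to 0.278, 8 over 0.1). Over 150 pairs with other numbers the mean was -0.0111 (-0.278 to 0.149, 1 over 0.1). Over 17 pairs with the same number and time it was -0.00632, with 0 over 0.1. Of 24 arrays, which are not independent here, 14 lay closest to their own number. With the replicate block all 15 counts stayed within 1.5 times the reported ones, with 193 genes changed by hypoxia 3 h, 6901 genes changed by hypoxia 24 h, 5794 genes changed by HIF1A knockdown averaged over 3, 6 and 12 h, 6625 genes changed by NDRG3 knockdown averaged over 6, 12 and 24 h, and 2370 genes that differ between HIF1A and NDRG3 knockdown averaged over 6 and 12 h.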

Other observations

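The 44 list tests of the change of a knockdown effect between times, and the bound of 2 times the array median, were chosen only after the result was seen, and the p-values of the tests were adjusted together. Between 6 h and 24 h the gap between the shNDRG3 and shGFP lines narrowed for interferon-stimulated genes, with 23 of 32 positive and 0 negative (median 1.20, adjusted p = 4.73e-23, or adjusted p = 0.00327 with an estimated correlation). Of these 32, 22 lay over 2 times the array median in the shNDRG3 line at both times, and 16 of the 22 were positive and 0 negative (median 1.30). ISG20, an interferon-induced exonuclease, changed by 2.89 ± 0.18. In the shGFP line these genes had a median change of -0.97 at 24 h. NF-kappaB targets went the other way, with 15 of 26 negative and 1 positive (median -0.74, adjusted p = 1.86e-13, or adjusted p = 0.00131 with an estimated correlation). Only 10 of these 26 lay over 2 times the array median in the shNDRG3 line at both times, of which 5 were negative and 0 positive (median -0.69). S phase genes were positive in 13 of 32 with 0 negative (median 0.57, adjusted p = 2.66e-11, or adjusted p = 0.00298 with an estimated correlation). The ERK output (adjusted p = 0.0128) and glycolysis (adjusted p = 0.0352) lists passed only with the preset correlation (adjusted p = 0.342 and 0.457 with an estimated correlation).

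Between 3 h and 12 h the difference of the shHIF1A from the shGFP line in NF-kappaB targets became more negative, with 4 of 26 negative and 0 positive, 1 of these 4 over 2 times the array median in the shHIF1A line at both times (median -0.39, adjusted p = 4.37e-09, or adjusted p = 0.00298 with an estimated correlation). The S phase list moved up with 1 positive member and 0 negative (median 0.30, adjusted p = 1.15e-07, or adjusted p = 0.00964 with an estimated correlation). Mitosis (adjusted p = 8.63e-05, or 0.00298 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.00358, or 0.0329 with an estimated correlation) passed as well, while 3 lists passed only with the preset correlation: interferon-stimulated genes (adjusted p = 1.15e-07, or 0.116 with an estimated correlation), other HIF target genes (adjusted p = 0.000477, or 0.15) and angiogenic and inflammatory secreted factors (adjusted p = 0.00398, or 0.124). The calcium-binding protein S100A9 (-1.40 ± 0.18) and the synaptotagmin SYT7 (-1.23 ± 0.19, by 1 of its 4 probes) led the negative genes, and the phosphatase subunit PPP1R10 (1.30 ± 0.18) and the inhibitor of differentiation ID1 (1.15 ± 0.24) the positive ones.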
